A study of Cuscuta pentagona and Solanum lycopersicum with 10 samples.

How the data were processed

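The series measured transcripts with the Affymetrix Tomato array in 10 RNA samples. Per the labels' protocols, dodder (Cuscuta pentagona, a parasitic plant without leaves that takes water, sugars and RNA from its host through haustoria) was grown on tomato, on Arabidopsis, on tobacco and on pumpkin. Dodder stems were taken at least 4 cm from the host, after 9 to 12 weeks of growth. Tomato host RNA came from leaf tissue of parasitized plants without attached dodder. Dodder on pumpkin was first grown on tomato, trained onto pumpkin and severed from tomato 2 weeks after new haustoria had formed. Dodder on Arabidopsis was grown in a growth room, and the plants of the other groups in a greenhouse. Host age at the start was 2 weeks for tomato, 4 weeks for Arabidopsis and pumpkin and 7 weeks for tobacco. RNA was extracted with TRIzol, treated with DNase and amplified and labelled with the Ovation Biotin system, which amplifies linearly.

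The samples fell into 3 tomato host arrays, 3 arrays of dodder on tomato and 4 arrays of dodder on other hosts, 1 on Arabidopsis, 1 on tobacco and 2 on pumpkin. The design text calls the replicates biological replicates, and each was a harvest of many stems. No array was left out of the comparisons.

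The deposited values are intensity, 1 per probe set and array. They are linear and never negative, have 1 decimal, and are not brought to a common mean or median, as read from the values. How the authors summarised or scaled them is not given in the sources used here. The median of all probe sets was 168.3, 138.6 and 108.1 on the tomato host arrays and 5.6, 4.2 and 6.2 on the arrays of dodder on tomato. It was 1.4 for dodder on Arabidopsis, 1.7 for dodder on tobacco, and 4.6 and 5.9 for dodder on pumpkin. The number of arrays, 1 to 3 per host, limits the precision of every comparison.

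The table held 10209 probe sets. The 108 control probe sets with the AFFX prefix were left out of the tests, which left 10101. Of these, 909 carry 1 gene symbol in the array annotation, 207 of them a placeholder starting with LOC. None carries several symbols and 9192 carry none. A gene is called named here if it has a symbol other than a placeholder. Probe sets without a symbol are given by their ID, printed in capitals. Genome positions were not used here. The 59 control probe sets for transcripts that were not spiked in served as the background, taken per array as their 95th percentile.

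Groups, comparisons, the rule for normalization, the gene lists and the rule for naming genes were chosen before the data were examined. That rule kept the deposited scale unless the 2% trimmed means of arrays of the same species differed over 1.2-fold. They ranged from 260 to 379 on the tomato arrays and from 2.21 to 8.60 on the dodder arrays, so quantile normalization was applied within each species. An offset of 16 was added before taking log2, and dim probe sets were kept. Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend over signal. All tests of single probe sets were two-sided, with p-values adjusted by Benjamini-Hochberg over all tested probe sets and a threshold of 0.05.

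Dodder on tomato was compared with dodder on the other hosts, which the design text uses as the control for dodder transcripts that bind tomato probes. Tomato host was compared with the same 4 controls and with dodder on tomato. Dodder on pumpkin was compared with dodder on Arabidopsis and tobacco in a fit of 3 groups, and dodder on tomato with dodder on pumpkin in a fit of 4 hosts. Probe sets higher in both dodder on tomato and tomato host were counted. That count was set beside the product of the 2 rates, beside 100 simulations in which unchanged groups share their controls, and beside all splits of the 4 controls into 2 and 2.

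The authors scored a transcript as present with a detection p of 0.06 in at least 2 of 3 replicates. Presence was approximated here from signal, with a probe set counted as on where it exceeded the median of its array. A presence candidate was on in at least 2 of 3 tomato arrays, in at least 2 of 3 arrays of dodder on tomato, and in none of the 4 control arrays. The same count was taken over all 35 splits of the 7 dodder arrays into 3 and 4.

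A tomato-like share was computed per dodder array over probe sets whose lowest tomato array was at least 8 times the mean of the dodder arrays. The share is the median, over these probe sets, of the excess over other control arrays divided by the same excess in tomato. It was tested by exact permutation of the arrays.

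Lists for 13 gene groups were fixed as search words, which were matched to gene symbols only and not to gene names or descriptions. A gene whose symbol did not match is missing from its list, as are PETE and ACT. Members of 1 list are not independent replicates of each other. They cover photosynthesis, defence, wounding and jasmonate, transport of sugars and water, long-distance mobile regulators, ribosomal proteins, translation factors and cytoskeleton, histones and cell cycle, heat shock, cell wall, ethylene, phenylpropanoids, and fruit ripening as a sign of another tomato organ. By symbol, the list for translation factors and cytoskeleton matched only 14-3-3 genes and 1 tubulin gene. That for histones and cell cycle matched only cyclins and cyclin-dependent kinases, and that for phenylpropanoids only chalcone synthases. These lists are named by what they hold, and other such genes may be on the array. The 12 lists with at least 3 probe sets were tested with camera from limma, with a preset correlation of 0.01 and with an estimated correlation. Camera compares a list with the other probe sets. Fry from limma was also run, and it tests only whether a list moves one way. Adjusted p-values of lists are over the 12 lists of a comparison.

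Named genes are the 12 largest rises and 8 largest falls that passed with arrays of the 2 groups not overlapping, 1 probe set per gene. Where fewer than 5 passed, the 5 of lowest p are given and said not to pass. Up to 5 per direction are given for the other comparisons and up to 3 per gene list. Means of single probe sets are on the normalized linear scale unless called deposited. Folds are ratios of geometric means without the offset. Where every array of the dimmer group was below its background, a fold is given as at least the ratio of the brighter group's geometric mean to that of the background in the dimmer group. Where only some arrays of the dimmer group were below background, the means are given and no fold.

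Alternatives covered the offset, centring each array on its median, quantile normalization over all arrays of a comparison, models without a trend or with 1 fit for all arrays, a filter on dim probe sets, weights for hosts, presence at other levels, leaving out pumpkin or tobacco, and leaving out each array. Values as deposited, scaling by the spiked hybridization controls, a block for array sets, presence by background and leaving out Arabidopsis and tobacco together were added after the data were seen. The methods were tested on simulated data made from these arrays with 200 changed probe sets. A log2 change of 3 was recovered for 96% to 100.0% of them. A log2 change of 1 was recovered for 67% in dodder on tomato against other hosts, 46% in tomato host against other hosts and 39% in tomato host against dodder on tomato. It was 56% for pumpkin against Arabidopsis and tobacco and 51% for dodder on tomato against pumpkin, with 9 false calls in the latter. With fewer changed probe sets the adjustment is stricter, so these rates do not give the power to find a few. In the real data LES.3624.1.S1_AT, at log2 1.20 in dodder on tomato against other hosts, did not pass (limma adjusted p 0.747). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. Detection calls and the scanned images were not used here.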

Results

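Dodder coils around a host and joins its vascular tissue, and the study asked whether tomato messenger RNA passes into dodder stems. Tomato leaf RNA (3 arrays), RNA of dodder on tomato (3 arrays) and RNA of dodder on Arabidopsis (1 array), tobacco (1 array) and pumpkin (2 arrays) were hybridized to the Affymetrix Tomato array. Dodder on hosts other than tomato gives the signal that dodder transcripts leave on tomato probes by themselves.

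Tomato RNA raised 8680 ± 361 (SD, n = 3) of the 10101 tested probe sets above background. Dodder on tomato raised 1487 ± 351 (SD, n = 3) and dodder on the other hosts 1276 ± 440 (SD, n = 4). Median intensity was 108.4 to 168.8 on tomato arrays and 1.4 to 6.2 on dodder arrays, where it lay below the background of 5.43 to 18.4. Arabidopsis and tobacco arrays of dodder had spiked BioB controls of 690 and 528, against 183 to 266 on the other 8 arrays. Across genes, which are not independent replicates, Spearman correlations of the arrays of dodder on tomato were 0.514 to 0.586 with each other, 0.476 to 0.532 with pumpkin arrays, and 0.156 to 0.184 with the Arabidopsis and tobacco arrays. Those 2 arrays, which correlated at 0.260 with each other, are called an array set below for their shared distance from the other 5 dodder arrays. Among comparisons of dodder arrays with each other, only that of dodder on tomato with dodder on pumpkin lies within a single array set. Tomato host against dodder on tomato uses neither of the 2 arrays.

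**Figure D1:**
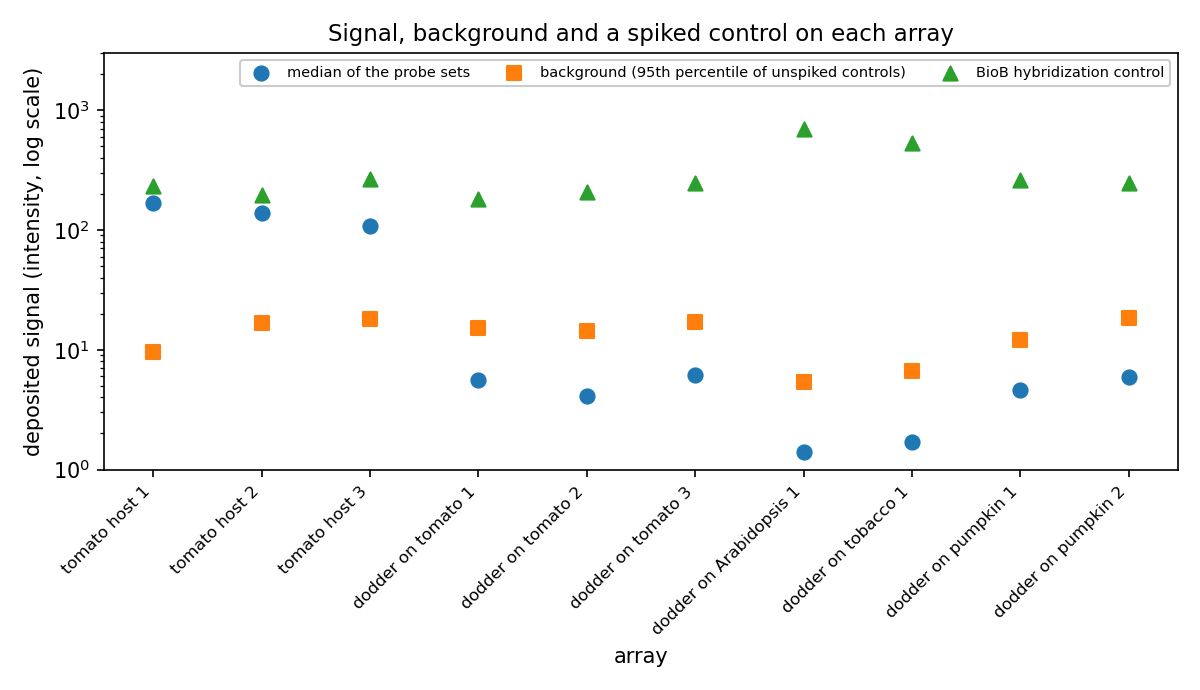
Median intensity, background and the spiked BioB control are drawn for each array on a log axis, 1 array per host for Arabidopsis and tobacco. The median was 168.8, 139.0 and 108.4 on tomato arrays and at most 6.2 on dodder arrays, and BioB was 690 and 528 on the Arabidopsis and tobacco arrays of dodder.

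Tomato host was compared with dodder on other hosts to show which transcripts the array reads in the host and not in dodder. Of the 12 named genes given here, 5 are on the list of photosynthesis genes. CAB6A and CAB4 encode chlorophyll a/b-binding proteins of the light-harvesting complexes, PSBO, PsbQ and PSBR encode proteins of the oxygen-evolving side of photosystem II, and PETE, which is not on that list, encodes plastocyanin. All 6 were higher in tomato leaf. CAB6A had a mean of 8841 ± 413 (SD, n = 3) in tomato and 7.18 ± 3.59 (SD, n = 4) in control dodder, where it was below background on all 4 arrays. The tomato mean was at least 654-fold the control background (log2 8.59, SE 0.22, adjusted p 2.94e-10).

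PSBO was at least 603-fold higher, CAB4 at least 579-fold and PETE at least 387-fold. PsbQ was at 6861 ± 871 (SD, n = 3) against 6.71 ± 7.94 (SD, n = 4), above background on 1 of the 4 control arrays, and PSBR at 8984 ± 25.9 (SD, n = 3) against 15.1 ± 7.34 (SD, n = 4), above background on 3 of them. The carbonic anhydrase gene ca2 was at least 394-fold higher on its brightest probe set, the glutamate decarboxylase gene gad2 at least 537-fold and ltpg1 at least 517-fold. Of the 3 other probe sets of ca2, the dimmest was at log2 1.04 and turned to -1.84 under centring and to -0.91 under quantile normalization over all arrays. TLRP, a tyrosine- and lysine-rich cell wall protein, was at 7392 ± 803 (SD, n = 3) against 5.84 ± 8.01 (SD, n = 4), above background on 1 control array. TCTP, the translationally controlled tumour protein, was at least 463-fold higher. LEMT1, a metallothionein, was at 7405 ± 623 (SD, n = 3), with 2 of the 4 control arrays above background. The adjusted p of these 12 genes was at most 1.84e-09, their log2 change was 8.07 to 8.59, and each was higher in 3 of 3 tomato arrays than in any control array.

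No named gene passed as lower in tomato. The 5 of lowest p were FESOD (log2 -0.36, adjusted p 0.0778), matriochka (-0.37, 0.0916), EXPA6 (-0.33, 0.147), PG2 (-0.24, 0.174) and the ripening regulator RIN (-0.26, 0.183), and these probe sets were dim in both groups. FESOD was higher on its other probe set (6.02, adjusted p 3.78e-09), and so was EXPA6 (0.77, adjusted p 0.00622), with 31.7 ± 5.04 (SD, n = 3) in tomato, but the latter turned to -2.08 under centring and to -3.29 under quantile normalization over all arrays. Without the second pumpkin array the dim probe sets of FESOD, matriochka and EXPA6 passed as lower (-0.48, -0.50 and -0.49, adjusted p 0.0182, 0.0257 and 0.0262). In all, 8672 probe sets were higher and 28 lower. Of the higher ones, 778 carry a gene symbol, placeholders included, and 5772 were below background on every control array. The median change of all probe sets was log2 2.86. Centring each array on its median, which forces both species to the same median, left 3741 higher and 4112 lower with a median of -0.06, and quantile normalization over all 7 arrays left 1099 higher and 843 lower with a median of -0.12. The 12 genes above passed under both on the probe sets named, with log2 5.23 to 5.70 and 3.34 to 6.53. Under centring the same dim probe sets of FESOD, matriochka, EXPA6, PG2 and RIN also passed as lower, at -3.23 to -3.13. Under quantile normalization those of FESOD, EXPA6 and RIN passed as lower (log2 of -2.22 or lower, adjusted p 0.0454, 0.0266 and 0.0414). In 1 fit over all 10 arrays those of FESOD and matriochka did (adjusted p 0.0488 and 0.0300). Over all alternatives the adjusted p ranged from at most 2.10e-07 to 0.325 for FESOD, 0.490 for matriochka, 0.773 for EXPA6 and 0.471 for RIN.

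The gene lists were compared between tomato host and dodder on other hosts. Over all probe sets 85.9% were higher in tomato host, and the counts of each list below are to be read beside that share. Of the 8672 higher probe sets, 5772 were below background on every control array, where the log2 change follows tomato signal alone. All 7 photosynthesis probe sets were higher, with 7 also adjusted over the list alone and a median log2 of 8.30, and all 7 passed under centring (median 5.39) and under quantile normalization over all arrays (4.94). The list exceeded the other probe sets (camera adjusted p 0.0211), which was lost at an adjusted p = 0.196 with an estimated correlation. All 6 probe sets of ribosomal proteins were higher, 6 adjusted over the list alone, with a median of 5.73 and RPL3 at 7.06, RPL37 at 5.92 and rpl38 at 5.44. All 8 probe sets of 14-3-3 and tubulin genes were higher, 8 adjusted over the list alone, with a median of 5.30, the tubulin gene TUB at 7.12 and the 14-3-3 genes TFT3 at 5.55 and tft8 at 5.05. Under centring all 6 and all 8 passed, with medians of 2.80 and 2.40, and under quantile normalization over all arrays 4 and 2 did, with medians of 2.61 and 1.41. Both lists had a camera adjusted p of 0.0406, and both an adjusted p = 0.196 with an estimated correlation. Without the first tomato array it was 0.0606 for both, and without tomato array 3 it was 0.0725 for both.

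Of 15 probe sets of long-distance mobile regulators, 8 were higher, 8 adjusted over the list alone, with a mean of 1.87 and a median of 0.92. Under centring 3 were higher and 9 lower, with a median of -1.98, and under quantile normalization over all arrays 1 and 4, with -1.31. GAI, which encodes a DELLA repressor of gibberellin responses, was at 5.19 (SE 0.20), and the Aux/IAA genes IAA16 and IAA17 at 5.57 and 4.57, while their other probe sets were at 2.06, turning to -0.83 under centring, and at 0.14, which did not pass. Fruit ripening genes had 3 of 6 higher, 3 adjusted over the list alone, with a mean of 1.76 and a median of 0.71. Under centring 2 were higher and 4 lower, with a median of -2.29, and under quantile normalization over all arrays 1 and 0, with -2.03. The phytoene synthase gene Psy1 was at 5.27, but at 0.43 on another probe set that did not pass, and the polygalacturonase gene PG2 at -0.24. E8 was at 0.98 and turned to -1.98 under centring and to -2.44 under quantile normalization over all arrays. Camera placed both lists below the other probe sets at an adjusted p of 0.0406, although their medians are positive, with an adjusted p = 0.301 with an estimated correlation for the regulators and an adjusted p = 0.196 with an estimated correlation for the ripening genes. Without the first tomato array the adjusted p was 0.109 for the regulators and 0.0606 for the ripening genes, for which it was 0.0711 without the second tomato array and 0.0792 without the first pumpkin array.

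Defence genes had 8 of 11 higher, 8 adjusted over the list alone (median 3.94), with the chitinases CHI3 at 5.94, CHI17 at 4.57 and CHI9 at 3.96. Under centring 5 were higher and 3 lower (median 0.99), and under quantile normalization over all arrays 1 and 1 (0.92), where CHI17 turned to -0.37. Cell wall genes had 27 of 29 higher, 27 adjusted over the list alone (median 3.72), with XTH16, a xyloglucan endotransglucosylase/hydrolase, at 8.01, the expansin gene EXP5 at 5.95 and the cellulase gene CEL8 at 5.68. Under centring 16 were higher and 8 lower (median 0.83), and under quantile normalization over all arrays 5 and 2 (0.54). Wound and jasmonate genes had 8 of 10 higher, 8 adjusted over the list alone, with the oxophytodienoate reductase genes OPR1 at 5.68 and OPR3 at 5.09 and the leucine aminopeptidase gene LAPA2 at 5.01. Their median was 3.09. Under centring 5 were higher and 4 lower (median 0.23), and under quantile normalization over all arrays 2 and 0 (-0.23). Ethylene genes had 20 of 27 higher, 20 adjusted over the list alone, with ACO6 at 6.48, EIL2 at 5.37 and EIL3 at 4.68. Their median was 2.51. Under centring 9 were higher and 12 lower (median -0.43), and under quantile normalization over all arrays 3 and 3 (-0.31).

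Transport genes had 7 of 9 higher, 7 adjusted over the list alone, with the aquaporin gene pip1 at 4.45, the sucrose synthase gene sus3 at 2.85 and the sucrose transporter gene SUT4 at 2.05, but at 0.32 on its other probe set, which did not pass. Their median was 2.05. Under centring 1 was higher and 5 lower (median -0.92), with SUT4 at -0.92, and under quantile normalization over all arrays 0 and 1 (-0.74), with sus3 at -1.71. All 9 probe sets of cyclins and cyclin-dependent kinases were higher, 9 adjusted over the list alone, with CDKA1 at 4.10, CycA3 at 3.76 and CYCD3 at 3.35, and a median of 2.52. Under centring 2 were higher and 4 lower (median -0.32), and under quantile normalization over all arrays none passed (0.12). Heat shock genes had 3 of 4 higher, 3 adjusted over the list alone, with Hsp90-1 at 5.80, HSP17-6 at 4.32 and HSP17.4 at 1.02, and a median of 2.67. Under centring 2 were higher and 2 lower (median -0.25), and under quantile normalization over all arrays 1 and 0 (0.09), with HSP17.4 at -1.83 and -0.89. Both probe sets of the chalcone synthase genes, CHS2 at 7.81 and CHS1 at 6.24, were higher, 2 adjusted over the list alone, and both passed under centring (median 4.17) and under quantile normalization over all arrays (4.00). The camera adjusted p was 0.465 for defence, transport and ethylene, 0.833 for wound and jasmonate, cell wall and cyclins and their kinases, and 0.922 for heat shock. For defence, wound and jasmonate, transport, ethylene and heat shock genes camera pointed down against the other probe sets while median and mean were positive.

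**Figure D2:**
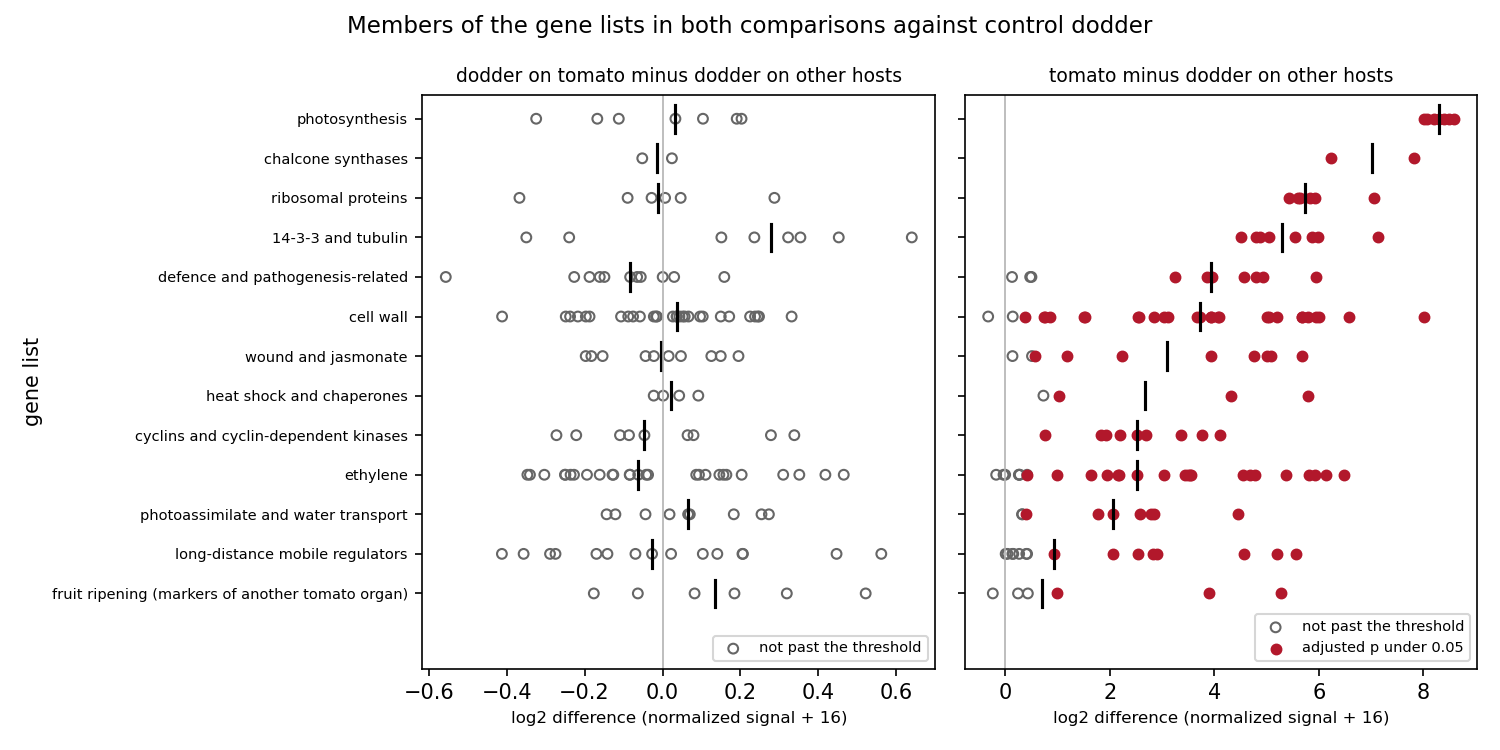
Log2 changes of the members of each gene list are drawn for dodder on tomato and for tomato host, each against dodder on other hosts, with a black bar at the median. In tomato host the median was 8.30 for photosynthesis and 0.92 for long-distance mobile regulators, the latter turning to -1.98 when arrays were centred and to -1.31 when quantile normalized over all arrays, and in dodder on tomato no member passed.

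Tomato host was compared with dodder on tomato to set host and parasite side by side. CAB4 was at least 623-fold higher in tomato (log2 8.72), PSBO at least 649-fold (8.66), TLRP at least 586-fold (8.61), TCTP at least 498-fold (8.42) and PsbQ at least 543-fold (8.41). Named genes that were lower in tomato included LysRS (-0.54, adjusted p 0.0254), named for a lysyl-tRNA synthetase, and matriochka (-0.36, adjusted p 0.0441). Matriochka was below background on all 6 arrays, and LysRS was above it on 1 array of dodder on tomato only and overlapped between the groups. RIN at -0.45, AGL11 at -0.21 and FER at -0.28 did not pass (adjusted p 0.082, 0.145 and 0.173). Over all alternatives the adjusted p of LysRS was 1.63e-06 to 0.0848 and that of matriochka 3.63e-06 to 0.133. LysRS did not pass without array 2 or 3 of tomato (0.0848 and 0.0701) or array 2 or 3 of dodder on tomato (0.0703 and 0.0838). Matriochka did not pass without any 1 of the tomato arrays (0.0838, 0.0750 and 0.0670) or without array 2 or 3 of dodder on tomato (0.0973 and 0.133), while RIN passed without array 3 of dodder on tomato (0.0021, range 9.19e-06 to 0.256) and FER without the first tomato array (0.0175, range 2.28e-06 to 0.468). In all, 8663 probe sets were higher and 44 lower, with a median log2 of 2.85. Centring left 3583 higher and 4036 lower and quantile normalization over the 6 arrays 2197 and 2203, and the 5 named genes stayed higher with log2 of at least 5.46 and 5.39.

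Dodder on tomato was compared with dodder on other hosts to find transcripts that might have come from tomato, and no named gene passed. The aquaporin gene Aqp2 had the lowest p among named genes, with 28.7 ± 4.32 (SD, n = 3) against 9.65 ± 3.88 (SD, n = 4), a log2 of 0.81 (SE 0.28, adjusted p 0.747). TUB had 12.3 ± 1.13 (SD, n = 3) against 2.23 ± 2.06 (SD, n = 4), a log2 of 0.64 (SE 0.23, adjusted p 0.747). The others of lowest p were AGL11 at 0.35, DET1 at 0.60 and MCA1 at 0.68, and among negative values STV3 at -0.72, TBG7 at -0.62, T12 at -0.59, CHI17 at -0.56 and MT4 at -0.53, all with an adjusted p of 0.747. The 3 other probe sets of MT4 were at -0.12, -0.03 and 0.38. GAI was at 0.45 (SE 0.25) and did not pass.

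Of 10101 probe sets, 3 were higher and 2 lower in dodder on tomato. None of the 5 has a gene symbol, so they are given by their probe set IDs, chosen after their values were seen. LES.3378.3.S1_A_AT had the smallest adjusted p (5.62e-04, log2 3.33, SE 0.52, a 12.8-fold ratio of geometric means). Its deposited mean was 1377 ± 538 (SD, n = 3) in dodder on tomato, 719 ± 79.2 (SD, n = 2) on pumpkin and 1951 ± 1299 (SD, n = 3) in tomato, and 8.2 on the Arabidopsis array, and its values overlapped between the groups after normalization. LES.2993.2.S1_AT was 4.53-fold higher (log2 1.79, SE 0.36, adjusted p 0.0138). Its deposited mean was 225 ± 73.8 (SD, n = 3) in dodder on tomato, 36.3 ± 32.3 (SD, n = 4) on other hosts and 188 ± 66.1 (SD, n = 3) in tomato, with all 4 control arrays above background.

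LES.1783.1.A1_AT was at least 3.29-fold higher (log2 1.72, SE 0.32, adjusted p 0.00566). Its deposited values in dodder on tomato were 156.9, 77.5 and 18.2, which are 4.38%, 2.16% and 0.508% of the tomato mean of 3584 ± 1436 (SD, n = 3), and the controls were at 2.88 ± 1.59 (SD, n = 4). LESAFFX.3499.2.S1_AT was lower (log2 -2.86, SE 0.51, adjusted p 0.00326), with deposited means of 23.8 ± 11.5 (SD, n = 3) and 218 ± 199 (SD, n = 4). LES.4954.1.A1_AT was lower (log2 -2.45, SE 0.43, adjusted p 0.00326), with 24.3 ± 31.6 (SD, n = 3) and 120 ± 55.2 (SD, n = 4). In dodder on tomato the former was above background on 2 arrays and the latter on 1.

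Unadjusted, 562 probe sets passed where chance gives 505. The count of 5 fell to 0 without the Arabidopsis array and to 0 without the tobacco array, to 3 without the first array of dodder on tomato, and was 16 and 17 without the first and the second pumpkin array. With a block for the array sets it was 0. The split of 3 higher and 2 lower became 4 and 0 under centring, 1 and 0 with values as deposited and 1 and 0 with scaling by the spiked controls, and those 2 scalings moved the median of all genes from -0.01 to 0.12 and 0.23. LES.1783.1.A1_AT was the only higher probe set that passed under all of these scalings, and its adjusted p was 0.132 without the Arabidopsis array, 0.380 without tobacco and 0.147 without the first array of dodder on tomato, within a range over all alternatives of 5.76e-06 to 1. LES.2993.2.S1_AT did not pass without the first or the second array of dodder on tomato (0.223 and 0.366), within a range of 0.00292 to 0.667.

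**Figure D3:**
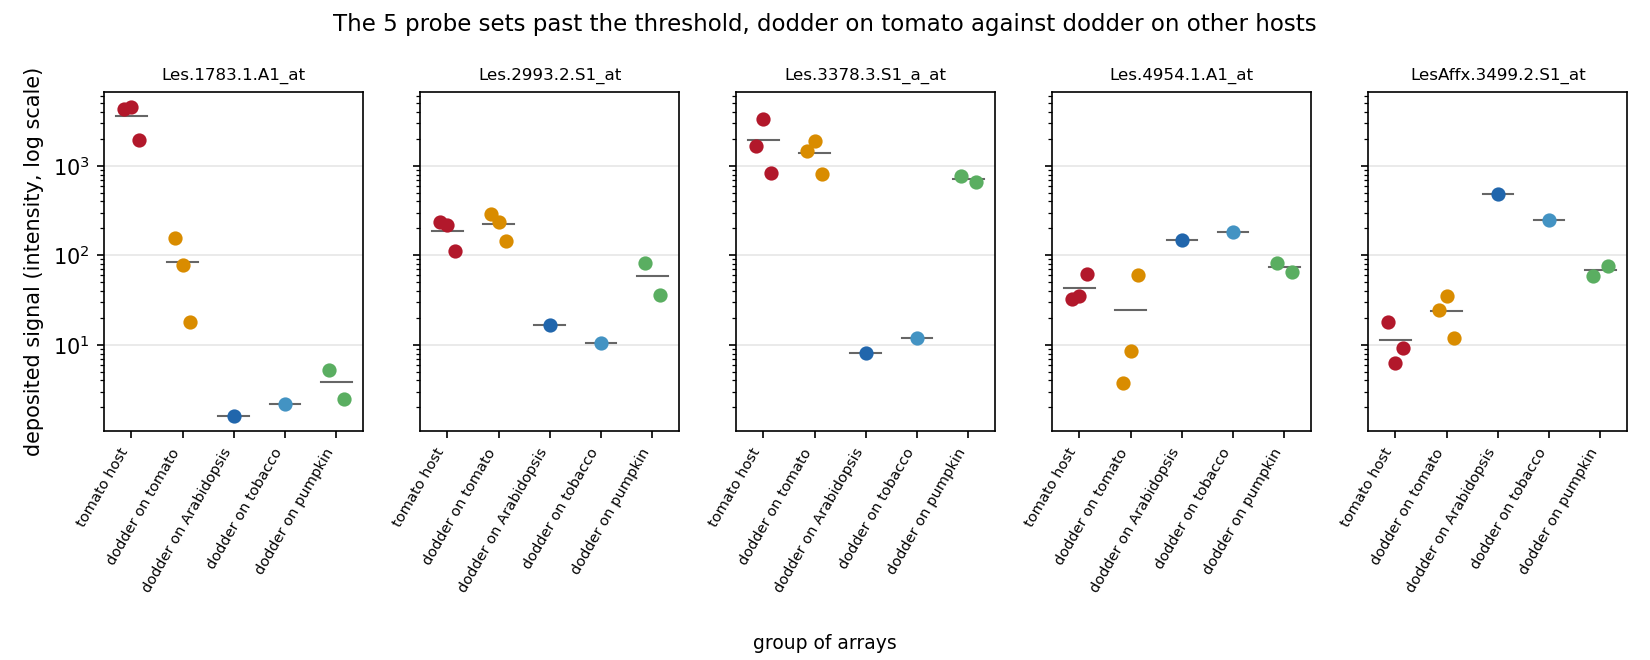
Deposited signal of the 5 probe sets that passed between dodder on tomato and dodder on other hosts is drawn by group on a log axis, with a grey bar at each group's mean. LES.1783.1.A1_AT had a mean of 84.2 ± 69.6 (SD, n = 3) in dodder on tomato and 3584 ± 1436 (SD, n = 3) in tomato host.

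No list passed in dodder on tomato, with 0 members higher or lower over all probe sets and 0 adjusted over the list alone in limma, for photosynthesis, ribosomal proteins, defence and the 10 other lists. The 14-3-3 and tubulin genes had the highest median, 0.28, with an adjusted p of 0.341 from camera and an adjusted p = 0.872 with an estimated correlation, and fry gave an adjusted p of 0.0787. All other lists had a camera adjusted p of 0.971, among them ripening genes (median 0.13), transport (0.07), cell wall (0.04), photosynthesis (0.03), heat shock (0.02), ribosomal proteins (-0.01), mobile regulators (-0.03), cyclins and their kinases (-0.05), ethylene (-0.06) and defence (-0.08). With scaling by the spiked controls all of these medians were positive, from 0.07 for defence to 0.69 for 14-3-3 and tubulin genes, where the median of all genes was 0.23. The wound and jasmonate median was at -0.003, and the 2 chalcone synthase probe sets had a median of -0.01 and no test. Median and mean differed in sign for photosynthesis, whose mean was -0.01, and for cyclins and their kinases, and for both the test direction differed from the mean.

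Transcripts that moved should be higher both in dodder on tomato and in tomato host. The 3 probe sets higher in dodder on tomato, LES.1783.1.A1_AT, LES.2993.2.S1_AT and LES.3378.3.S1_A_AT, were all also higher in tomato host, with log2 7.45, 1.85 and 3.47. The latter pair did not keep this under scalings that force both species together, as LES.2993.2.S1_AT turned to -0.89 under centring (adjusted p 0.0300) and to -4.34 under quantile normalization over all arrays (0.00112). LES.3378.3.S1_A_AT was at 0.62 under centring and turned to -1.58 under quantile normalization. The product of the 2 rates gives 2.58, since 85.9% of all probe sets were higher in tomato host. Simulations with shared controls gave 0, but both groups were unchanged in them, unlike tomato host here, so that 0 cannot be set against the 3. The count was 1 without the first array of dodder on tomato, 0 without the Arabidopsis array, 0 without the tobacco array, and 10 and 7 without the first and second pumpkin array. With the controls split between the 2 comparisons it was 41 when Arabidopsis and tobacco served as the controls of dodder on tomato, and 0 in the other 5 splits.

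By the signal-based presence rule, 91 probe sets were on in tomato and in dodder on tomato and off in all control dodder. The named ones were DXS, which encodes the first enzyme of the plastid isoprenoid pathway, GSH1, named for glutamylcysteine synthetase of glutathione synthesis, the GRAS gene GRAS6 and the 14-3-3 gene tft8. None of them passed between dodder on tomato and other hosts, where DXS was at log2 0.53 (SE 0.24), GRAS6 at 0.30, tft8 at 0.24 and GSH1 at 0.22. In tomato host they were at 5.64, 3.63, 5.05 and 4.78. Other groupings of the 7 dodder arrays into 3 and 4 gave 76 to 269 such probe sets with a median of 115, and 31 of the 35 groupings, the real one included, gave at least 91. The count was 40, 49 and 46 without each array of dodder on tomato, 157 and 165 without Arabidopsis and tobacco, and 223 and 191 without each pumpkin array. Within the single array set, with only pumpkin as control, it was 327, and the other groupings of these 5 arrays gave 297 to 358.

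**Figure D4:**
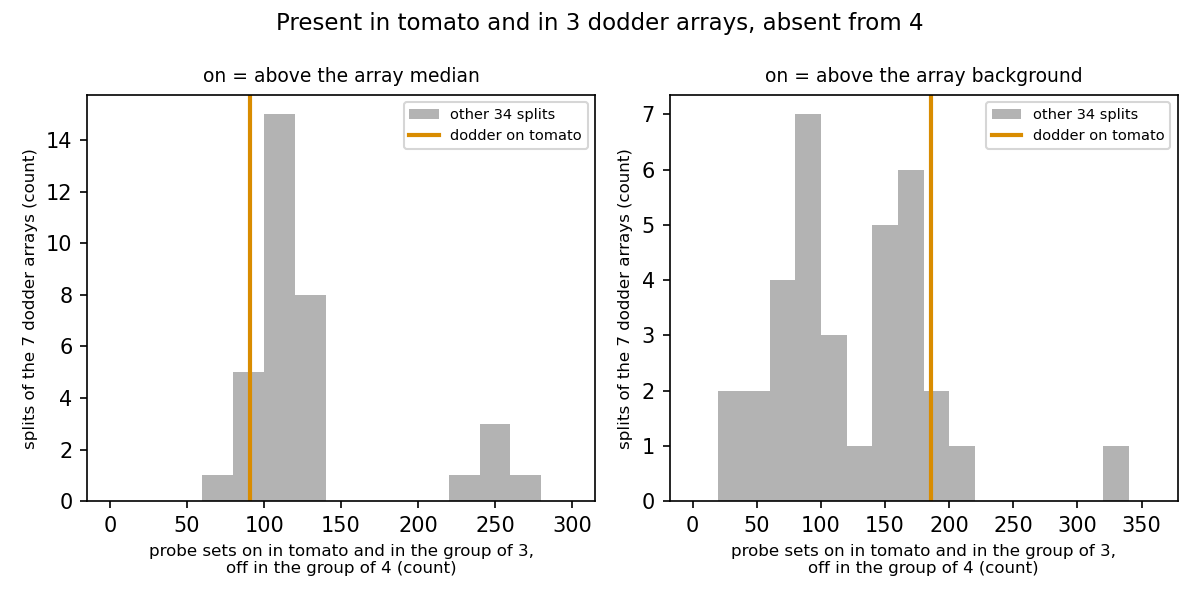
Counts of presence candidates over the 34 other groupings of the 7 dodder arrays are drawn as histograms, with the real grouping marked. The real count was 91 by the array median, where other groupings reached 269, and 186 by the background of each array, where they reached 332.

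Tomato-specific probe sets, 6868 of them led by photosynthesis genes such as CAB6A, were also examined together. The tomato-like share was 0.309%, 0.0124% and 0.383% on the arrays of dodder on tomato and -0.761%, -0.600%, 0.148% and 0.50% on Arabidopsis, tobacco and the 2 pumpkin arrays. The means were 0.235% ± 0.196 (SD, n = 3) and -0.178% ± 0.601 (SD, n = 4). The difference of 0.413 points had an exact permutation p of 0.2 one-sided, with 0.0286 the smallest possible, and 0.4 two-sided. It turned to -0.832 points when arrays were divided by their median (exact permutation p 0.771 one-sided, range over its alternatives 0.1 to 0.771). Within the single array set the difference was 0.00825 points, with an exact permutation p of 0.6 one-sided and a smallest possible p of 0.1.

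Dodder on tomato was compared with dodder on pumpkin, which had also been started on tomato, and no named gene passed. The actin gene ACT was at log2 0.98 (SE 0.24), Aqp2 at 0.76 (SE 0.19), TUB at 0.67 (SE 0.18), the lycopene cyclase gene LCY1 at 0.87 and AGL11 at 0.37, and on the other side PRO1 at -0.74, AREB1 at -0.60, the phosphate transporter gene PT2 at -0.57, the arginine decarboxylase gene adc1 at -0.34, against 0.11 to 0.22 on its 3 other probe sets, and CIP1 at -0.19. With a block for replicate numbers, fitted only on arrays 1 and 2 of both groups, ACT and LCY1 passed. Their adjusted p was 0.00919 and 0.0330, with ranges over all alternatives up to 1. That fit left out array 3 of dodder on tomato, which had the lowest normalized values of that group for both genes (16.4 and 8.1). The passes can therefore not be credited to the block alone, and the numbers are not known to pair the samples. In limma 0 of 10101 probe sets passed and 571 did unadjusted, where chance gives 505, and the smallest adjusted p was 0.872. The 5 probe sets that differed between dodder on tomato and all other hosts were chosen in a comparison that shares these 5 arrays, and none passed here (adjusted p 0.872), with LES.1783.1.A1_AT at 1.78 (SE 0.54), LES.2993.2.S1_AT at 1.66 (SE 0.33), LES.3378.3.S1_A_AT at 1.42 (SE 0.52), LES.4954.1.A1_AT at -1.37 (SE 0.46) and LESAFFX.3499.2.S1_AT at -1.18 (SE 0.33).

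Dodder on pumpkin was compared with dodder on Arabidopsis and tobacco, because only the former had a tomato history. The named genes that passed were higher on 2 of 2 pumpkin arrays than on either other array. DHS was at 36.1 ± 2.28 (SD, n = 2) against 2.64 ± 1.12 (SD, n = 2), at least 2.45-fold (log2 1.48, SE 0.28, adjusted p 0.0214). SAHH, which encodes S-adenosylhomocysteine hydrolase of the methyl cycle, was at 96.0 ± 18.4 (SD, n = 2) against 28.5 ± 2.64 (SD, n = 2), 3.34-fold (1.32, adjusted p 0.0485). The size of its change depended on scaling. Its deposited values were 130.8 and 78.4 against 9.5 and 11.9, and its log2 was 0.79 to 2.42 over all alternatives. GAL83, a subunit of SNF1-related kinase, was at least 2.29-fold higher (1.39, adjusted p 0.0239), ME2 at least 2.02-fold (1.31, adjusted p 0.0311) and the ribosomal protein gene RPL8 at least 2.50-fold (1.23, adjusted p 0.0497). Named genes on the other side did not pass, with TGAS118 at -1.28 (adjusted p 0.0648), LEMT1 at -1.12 (0.0731), WRKYIId-1 at -1.01, SCOA at -0.90 and ca2, on another probe set than above, at -0.61, against -0.15 to 0.02 on its 3 others.

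In this comparison 30 probe sets were higher and 34 lower. LES.4422.1.A1_AT was 6.32-fold higher (adjusted p 1.86e-05), and LESAFFX.33796.2.S1_AT and LESAFFX.65210.1.A1_AT were 8.55-fold and 12.3-fold lower (adjusted p 2.40e-04 for both). Quantile normalization gave LES.4422.1.A1_AT the same value, 1213.6, on both pumpkin arrays and all 3 arrays of dodder on tomato. Its small p therefore rests partly on spread that the normalization took away. Its deposited values were 1701.9 and 1577.5 on pumpkin against 66.8 on Arabidopsis and 98 on tobacco. LES.3378.3.S1_A_AT was also higher on pumpkin (log2 3.80, SE 0.43) and LESAFFX.3499.2.S1_AT lower (-3.36), while LES.1783.1.A1_AT was at -0.11 (adjusted p 0.929). Host, tomato history and array set all differ between these groups, as do the growth place for Arabidopsis and the host age at the start for tobacco. The difference cannot be assigned to any of them. The split of 30 higher and 34 lower became 223 and 358 under centring, 476 and 8 with values as deposited, where the median of all genes was 0.24, and 468 and 2 with scaling by the spiked controls, where it was 0.32. The 5 named genes passed in all 3. In 1 fit over all 10 arrays none of the 5 passed (adjusted p 0.0621 to 0.174). With offset 64 SAHH, ME2 and RPL8 did not pass (0.134, 0.0655 and 0.0578), nor did RPL8 with offset 1 (0.0544). LESAFFX.33796.2.S1_AT did not pass with values as deposited (log2 -1.41, adjusted p 0.0878) or with scaling by the spiked controls (-0.62, 0.371), within a range of 3.59e-05 to 0.371. LESAFFX.65210.1.A1_AT did not pass with scaling by the spiked controls (-0.91, adjusted p 0.120, range 1.20e-04 to 0.120). LES.3378.3.S1_A_AT did not pass without the first pumpkin array (0.0780, range 2.05e-07 to 0.0793). The total of 64 was 35 and 39 without the first and second array of dodder on tomato, 317 without Arabidopsis, 344 without tobacco, and 11 and 13 without each pumpkin array.

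The named genes of this comparison depended on single arrays. None of DHS, GAL83, SAHH, ME2 and RPL8 passed without the first pumpkin array (adjusted p 0.152 to 0.249) or without the second (0.209 to 0.241), where a lone array is assumed to vary like the others. Without the first array of dodder on tomato GAL83, SAHH, ME2 and RPL8 had adjusted p of 0.0628, 0.118, 0.0735 and 0.109. Without the second SAHH, ME2 and RPL8 had 0.0768, 0.0711 and 0.102, and without array 3 SAHH and RPL8 had 0.0540 and 0.0660. SAHH had 0.0714 without Arabidopsis, and DHS and RPL8 had 0.0511 and 0.0746 without tobacco. On the other side ca2, SCOA, LEMT1 and WRKYIId-1 passed as lower on pumpkin without tobacco (0.0206, 0.0395, 0.0347 and 0.0261), and ca2 and SCOA without Arabidopsis (0.0194 and 0.0292). Over all alternatives the adjusted p was 0.00249 to 0.217 for DHS, 0.00181 to 0.241 for GAL83, 0.0012 to 0.249 for SAHH, 0.00245 to 0.209 for ME2 and 0.00249 to 0.241 for RPL8.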

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

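The tests of array sets, host relatedness, bulk carry-over, accidental separation and controls above background were chosen only after the results were seen, as was the count of other groupings for presence by background.

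The 4 control dodder arrays were examined in 56 groups of values, those of named or called probe sets and that of the tomato-like share. In 4 of these groups, all of them probe sets, 1 array lay far from the other 3. Chance gives about 1 in 20 groups, 2.8 here. The gap to the nearest array took up 0.984 of the whole range for GAI, with a deposited value of 11.2 on the first pumpkin array against 1.1 to 4.8 on the others. It took up 0.914 for CHS1, with 6.3 on the tobacco array against 0.2 to 2.0. It took up 0.842 for DET1, with 0.4 on the tobacco array against 2.1 to 6.9. It took up 0.831 for LES.1783.1.A1_AT, with the second pumpkin array apart on the normalized scale and a deposited value of 2.5 within the 1.6 to 5.2 of the others. All 4 were near or below background on these arrays.

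A control probe set outside the tests, for the 5' end of tomato actin, was higher in dodder on tomato than in control dodder. It read 78.2, 60 and 103.7 in dodder on tomato and at most 50.6 on other hosts, where it was 1.7 on Arabidopsis, 5.5 on tobacco and 50.6 and 45.7 on pumpkin. The tomato mean was 1234. The other 2 actin probe sets did not separate, with 77.6, 49.8 and 73.2 against 65.6 on the first pumpkin array for the middle, and 17.1, 7.4 and 29.6 against 17.5 for the 3' end. Of the 22 control probe sets for tomato genes, 2 separated the groups, the other at values below background. Chance would separate 0.629 if the 7 dodder arrays were alike. On these deposited values the Arabidopsis and tobacco arrays were dim throughout, with medians of 1.4 and 1.7, so that number cannot tell whether 2 is an excess.

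The Arabidopsis and tobacco arrays of dodder stood apart from the 5 other dodder arrays. A hybridization or scan that differed is a candidate explanation that stays open, since the lower of these 2 arrays was 1.98 times the highest of the other 8 for BioB, 1.76 for BioC and 1.62 for BioD, but 0.828 for Cre, which a uniform gain would have raised too. Relatedness of the host to tomato cannot be told apart from it, because tobacco, a relative of tomato, has only 1 array, which belongs to this set, and its correlation with dodder on tomato differed from that of pumpkin by -0.331 (mean rank correlation across genes). An effect of having grown on tomato cannot be told apart from it, because the 64 probe sets between pumpkin and these 2 arrays compare array set and tomato history at once. The growth place differed only for Arabidopsis and was not tested, and neither was host age at the start.

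LES.1783.1.A1_AT was higher in dodder on tomato and bright in tomato host, and it is the probe set closest to what a transcript that moved would show. It stood at 2.27% of its tomato level in dodder on tomato (4.30%, 2.08% and 0.428% on the 3 arrays). Tomato tissue or RNA carried over in bulk at that level is argued against by 154 brighter tomato-specific probe sets. Their median was 0.0664% and their upper quartile 0.152%, although 2 of the 154 stood as high or higher, up to 3.91%. The 154 were not chosen for high values in dodder on tomato. LES.1783.1.A1_AT was, so its distance from their median was partly fixed in advance and is no evidence by itself. A difference between array sets would raise pumpkin too. Pumpkin stood at a log2 of -0.11 (SE 0.46) from Arabidopsis and tobacco, with all of these arrays below background. Such a difference still cannot be told apart, because the log2 difference of 1.78 from pumpkin (SE 0.54, adjusted p 0.872) is over 2 SE but was measured on arrays that had served to choose the probe set. Accidental separation of 1 of many bright probe sets stays open, because 4 of the 35 groupings of the 7 dodder arrays separated as many bright tomato-specific probe sets, 43 in the real grouping and 78 in the highest other. Movement of this transcript from tomato into dodder therefore remains a hypothesis, which may be followed up with a sequence-specific test.

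LES.2993.2.S1_AT and LES.3378.3.S1_A_AT were also higher in dodder on tomato. Both were above background on 4 of 4 control arrays, but dodder on the 2 pumpkin arrays had been started on tomato. On Arabidopsis and tobacco LES.2993.2.S1_AT read 16.6 and 10.6 and LES.3378.3.S1_A_AT 8.2 and 11.8, against backgrounds of 5.43 and 6.64. These values are near the floor, so they cannot settle whether tomato RNA was the only source of the signal. In dodder on tomato LES.2993.2.S1_AT stood at 154%, 127% and 77.0% of its tomato mean, and LES.3378.3.S1_A_AT at 74.3%, 96.1% and 41.3%. With tomato RNA as the only source, dodder stems would have to hold amounts near those of tomato leaf. Both probe sets were chosen for high values in dodder on tomato, so that source stays open. For LES.2993.2.S1_AT a difference between array sets as the whole cause would leave no difference from pumpkin. The log2 difference from pumpkin was 1.66 (SE 0.33, adjusted p 0.872), and pumpkin exceeded Arabidopsis and tobacco by only 0.27 (SE 0.34). That cause still cannot be told apart, because the 1.66 was likewise measured on arrays that had served to choose the probe set. For LES.3378.3.S1_A_AT a difference between array sets is a candidate explanation, since pumpkin exceeded Arabidopsis and tobacco by a log2 of 3.80, more than the 1.42 between dodder on tomato and pumpkin. A dodder transcript that responds to the host stays open for both and was not tested.

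Other groupings of the same arrays show where chance can be excluded. For dodder on tomato against other hosts it cannot, as 6 of 35 groupings gave at least the 5 probe sets of the real one, and the highest other gave 22. That highest grouping put Arabidopsis, tobacco and the second pumpkin array together, and all 5 groupings with Arabidopsis and tobacco in the group of 3 gave 11 to 22, so these groupings follow the array set. With the array set as a block the count was 0, and in limma 0 passed between dodder on tomato and pumpkin, with 571 unadjusted. For probe sets higher in both, chance cannot be excluded either, with 6 of 35 groupings giving at least 3 and the highest other 10.

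For presence candidates chance cannot be excluded, with 31 of 35 groupings giving at least 91 and the highest other 269, several of them with Arabidopsis and tobacco together. By the background of each array 5 of 35 gave at least 186 and the highest other 332. For gene lists in dodder on tomato the real count of 0 is reached by all 35 groupings whatever the data, so this decides nothing. For tomato host against other hosts chance can be excluded, as only the real grouping, 1 of 35, gave 8700 probe sets, and the highest other gave 4010. Of its gene lists 5 passed in the real grouping, 1 of 35, and 3 in the highest other, with the preset correlation. Regrouping arrays asks only whether tomato arrays differ from dodder arrays. It cannot tell whether a list differs from the other probe sets by chance. With an estimated correlation none of the 5 passed, at an adjusted p of 0.196 to 0.301, and camera placed 2 of the 5 below the other probe sets. Tomato host against dodder on tomato has 10 groupings, too few for a share under 0.05, with 8707 probe sets in 1 of them and 0 in the highest other.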

How the results depend on the processing

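Values as deposited, scaling by spiked controls, the array set as a block, presence by background and leaving out Arabidopsis and tobacco together, or pumpkin for probe sets higher in both, were chosen after seeing the data. Where no cause is named below, the cause was not tested. Between dodder arrays signal over background limits what can be seen, since 5824 probe sets were above background on no dodder array. Of the values of named genes and of other probe sets given by ID under alternatives, 2403 kept direction and side of the threshold, 125 no longer passed, 33 newly passed and 10 reversed. Quantile normalization over the arrays of a comparison is identical to the main one for the 3 comparisons of dodder arrays only.

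Dodder on tomato against other hosts gave 5 probe sets. It gave 11 with offset 1, 0 with offset 64, 1 without a trend, 3 in 1 fit over all 10 arrays, 1 as deposited, 1 scaled by spiked controls, 10 with control hosts weighted equally, 88 without pumpkin, 0 without tobacco, 0 with the array set as a block and 0 without Arabidopsis and tobacco. Leaving out 1 array gave 0 to 17, with 0 without Arabidopsis or tobacco and 17 without the second pumpkin array. Leaving out arrays also leaves fewer samples.

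Tomato host against other hosts, 8700, became 1942 under quantile normalization over its arrays, and tomato host against dodder on tomato, 8707, became 4400. By construction that setting forces tomato and dodder arrays to the same distribution, and centring forces them to the same median. Leaving out 1 array gave 8563 to 8679 and 8478 to 8787. Under that quantile normalization CHI17 reversed to -0.37, sus3 to -1.71, HSP17.4 to -0.89, E8 to -2.44, LES.2993.2.S1_AT to -4.34 and LES.3378.3.S1_A_AT to -1.58. Under centring SUT4 reversed to -0.92, HSP17.4 to -1.83, E8 to -1.98 and LES.2993.2.S1_AT to -0.89.

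Dodder on pumpkin against Arabidopsis and tobacco, 64, became 97 with offset 1, 581 centred, 122 without a trend, 21 in 1 fit, 484 as deposited and 470 scaled by spiked controls, and 11 to 344 when 1 array was left out, 11 without the first pumpkin array and 344 without tobacco. Dodder on tomato against pumpkin, 0 in limma with 571 unadjusted, became 3 centred and stayed at 0 when any 1 array was left out.

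With a replicate block, tomato host vs dodder on tomato gave 8712 and dodder on tomato against pumpkin 27. The numbers are not known to pair the samples. Deviations of arrays with the same number correlated at 0.0336, 0.00775 and 0.0405 across genes between tomato and dodder on tomato, and at -0.00842 between pumpkin and dodder on tomato, below 0.1. Most probe sets on dodder arrays were below background, where deviations are mostly noise, so these correlations cannot exclude pairing.

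Probe sets higher in both, 3, became 0 with offset 64, 1 under quantile normalization, 1 without a trend, 0 in 1 fit, 1 as deposited, 1 scaled by spiked controls, 0 without Arabidopsis and tobacco, 43 without pumpkin, and 41, 0, 0, 0, 0 and 0 in the splits of the controls. Leaving out 1 array gave 0 to 10, with 0 without Arabidopsis or tobacco and 10 without the first pumpkin array. Presence candidates, 91, became 22 when all 3 arrays of dodder on tomato had to be on, 601 without pumpkin, 186 by background and 327 without Arabidopsis and tobacco, and 40 to 223 when 1 array was left out, 40 without the first array of dodder on tomato and 223 without the first pumpkin array. The tomato-like share, a difference of 0.413 points, reversed to -0.832 when arrays were divided by their median (exact permutation p 0.771 one-sided, range over its alternatives 0.1 to 0.771), and was 0.284 to 0.535 when 1 array was left out.

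For gene lists in tomato host, camera with an estimated correlation left the medians at 8.30 for photosynthesis, 0.92 for mobile regulators, 5.73 for ribosomal proteins, 5.30 for 14-3-3 and tubulin and 0.71 for ripening, without a pass. Fry, which tests only one-way movement, passed defence at 3.94, wound and jasmonate at 3.09, transport at 2.05, cyclins and their kinases at 2.52, heat shock at 2.67, cell wall at 3.72 and ethylene at 2.51. Under quantile normalization mobile regulators, 14-3-3 and tubulin, and ripening no longer passed, at -1.31, 1.41 and -2.03, nor did mobile regulators without Arabidopsis and tobacco, at 0.99. Leaving out 1 array gave 0.80 to 1.07 for mobile regulators, not passing without the first tomato array. It gave 5.68 to 5.81 for ribosomal proteins and 5.24 to 5.34 for 14-3-3 and tubulin, not passing without tomato array 1 or 3. It gave 0.51 to 0.86 for ripening, not passing without the first or second tomato array or the first pumpkin array.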

Other observations

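Of the gene lists with at least 3 probe sets, defence genes varied most among the 3 tomato leaf samples. The chitinase gene CHI3 had deposited values of 751.7, 603.2 and 3771.8, the thaumatin-like PR-5 339.5, 293.3 and 1477.3, the subtilase P69B 272.8, 505.2 and 1490.0, PR-P2 164.4, 256.3 and 926.3, and PR1b1 83.4, 361.3 and 581.7. Array 3 had the highest of these but the lowest for the subtilase P69A with 341.8, 178.4 and 65.2, for CHI17 with 810.3, 920.9 and 462.9 and for NP24-I with 17.6, 19.4 and 3.2. Across all tested probe sets tomato array 3 also stood apart. Its Spearman correlation was 0.923 with array 1 and 0.947 with array 2, which correlated at 0.970 with each other. The median SD of the defence list was 0.82 on the log2 scale, above all of 10000 random lists of probe sets of like brightness, whose median was 0.29. Cell wall genes followed with 0.55 against 0.27, also above all random lists. Photosynthesis genes had 0.13 against 0.21, at percentile 13.5 of random lists, and 14-3-3 and tubulin genes 0.13 against 0.25, at percentile 4.35. Single genes ranged wider still, with TPP3 at 4369.2, 2635.1 and 79.1 and the peroxidase gene CEVI-1 at 307.4, 1454.7 and 2851.5. These lists of genes are not independent replicates, the comparison was chosen after the values were seen, and unparasitized tomato was not analysed here.

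Some tomato probes read dodder RNA whatever the host. Above background on all 7 dodder arrays were 100 probe sets, and 5 of them are named. SAHH, S-adenosylhomocysteine hydrolase, had a deposited mean of 98.4 ± 70.6 (SD, n = 7) in dodder and 3542 in tomato. The superoxide dismutase genes SODCC.1 and SODCP.2 had 25 ± 13.2 (SD, n = 7) and 17.4 ± 6.82 (SD, n = 7) in dodder and 3420 and 1556 in tomato. CLPP2 had 24.1 and ACI29 had 23.9 in dodder.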
